A study of Homo sapiens with 24 samples.

How the data were processed

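The series holds RNA-seq of MV4-11 cells in 24 libraries, 3 for each combination of line (naive or entospletinib-resistant), agent (entospletinib or DMSO) and time (8 h or 24 h). Per the labels' protocols, libraries were made with a stranded poly(A) kit and read as single ends of 75 bp. Resistant cells were selected over 5 months at doses rising from 500 nM to 5 µM, and DMSO stayed under 0.001%, per the labels. The labels give the treatment dose as 700 with the unit mM, which does not match the scale of the selection doses; the unit is left open and no result uses it. The deposited table holds the authors' raw counts, as whole numbers per gene for 25728 gene symbols, with no normalization. Per the submitters' processing notes, reads were checked with FastQC 0.11.5, aligned with TopHat2 2.1.1 to GRCh37 (hg19) and counted with featureCounts. The annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. Genes that overlap a neighbour or have close copies are therefore uncertain, such as HOXA9 within the joint HOXA10-HOXA9 transcript unit, HLA class II genes, MT1H, ZNF761 with TPM3P9 and N4BP2L2-IT2. A further 28 names in the table are dates in the style of a spreadsheet and were kept as rows but not named. Mitochondrially encoded genes are not analysed here.

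Total counts per library ran from 4871769 to 28846226. Analyses used R 4.3.3. The main test was the quasi-likelihood test of edgeR 4.0.16 on the counts as deposited, with one mean per group and all 24 libraries in one fit (16 residual degrees of freedom), TMM factors, filterByExpr, robust dispersion and Benjamini-Hochberg adjustment; 13440 genes were tested and the common biological coefficient of variation was 0.108. A gene was called at an adjusted p under 0.05. Changes are log2 differences with standard errors (SE), and levels are counts scaled to library size (CPM) as mean ± SD of 3 libraries. Each SE was derived from the test, as the size of the change divided by the square root of the quasi-likelihood F statistic. Comparisons were drug against DMSO in each line and time, resistant against naive with DMSO at each time, the difference of the drug responses between lines at each time, and the difference between times in naive cells. The 26 gene lists were fixed before the data were examined; 25 could be tested, with 14 members not found in the table and 3 found under an older symbol. Lists were tested with camera (limma 3.58.1) with its preset correlation of 0.01, adjusted over lists within a comparison. They were tested again with an estimated correlation and with fry. Some lists share members, so their counts are not independent. MCM4 is in the MYC target and replication lists, and DUSP6 and ETV5 are in the ERK output and STAT5 and FLT3 lists. BCL6 is in the STAT5 and FLT3 and FOXO lists.

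Genes named in the text follow a rule also fixed before the data were examined. It takes SYK, FLT3, MYC, HOXA9, MEIS1, PIM1, DUSP6, NRAS and PTPN11 in every comparison. In each pairwise comparison it adds the 8 largest rises and 8 largest falls among called genes with an average log2 CPM of 2 or more, a symbol that is not a clone name, and groups whose libraries do not overlap. It adds the 4 members with the smallest p from each called list, and the 5 most positive and 5 most negative called genes of each difference of responses. Some genes that the rule selects are not reported here. Genes outside the rule are said to be so where they appear.

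The response score is the mean, over a set of genes, of a treated library's log2 CPM (prior count 2) minus the mean of the DMSO libraries of its line and time, signed by the direction in the set. Sets were the genes called in naive cells at the other time with a change of 1 log2 unit or more, so that no library both chose and scored a gene. Scores were compared by an exact permutation test.

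On simulated data with 200 changed genes in the naive 24 h drug comparison, run on 13428 genes, the test called 56.7% of genes changed 1.5-fold, 91% of those changed 2-fold and 95.5% of those changed 4-fold, with 14 false calls; in an unchanged resistance comparison at 24 h it called 0. The simulated counts were drawn independently for each gene, without the GC trends that differ between the real libraries, so these rates do not cover such trends. Another split of the real libraries in the resistance comparison at 24 h called 2967 genes. Alternatives were RLE, upper-quartile or no factors, DESeq2 1.42.0, no filter, a filter of 1 CPM in 3 libraries, a fit of only the groups compared, a block for the replicate number, and leaving out each library. A GC correction (a spline with 5 degrees of freedom per library on transcript GC content, known for 97% of tested genes), removal of CHD4, thinning of all libraries to the lowest total left without CHD4 (4869788 counts, CHD4 removed as well) and the comparison of times with DMSO were added after seeing the data. GC content came from GENCODE 29 transcripts matched by symbol (23018 genes) or by another symbol (856); the order of neighbouring genes came from the GRCh38.p14 gene table, and no coordinate is given because the counts use another build. The T and NK, B lymphoid, erythroid and megakaryocyte, and epithelial and stromal lists stood for other cell types.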

Results

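MV4-11 is an acute myeloid leukaemia line that carries an MLL fusion and an activating FLT3 duplication, and entospletinib is an inhibitor of the kinase SYK. RNA was sequenced from naive MV4-11 cells and from a derivative made resistant to entospletinib over 5 months, each treated with entospletinib or with the solvent DMSO for 8 h or 24 h. The 24 libraries formed 8 groups of 3. Their total counts ran from 4871769 (resistant, drug, 24 h, replicate 3) to 28846226 (resistant, DMSO, 8 h, replicate 1). In the deepest library CHD4, a chromatin remodeller, held 10235670 counts or 35.48% of the total, against 13767 and 11306 counts in the other libraries of its group. Without CHD4 its total was 18610556. Every pair of libraries within a group differed by more than sampling noise, at a chi-square per degree of freedom from 1.67 to 54.4. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

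SYK, the drug's target, was expressed in naive cells with DMSO (161 ± 4.43 CPM, counts scaled to a common library size, SD, n = 3, at 8 h and 144 ± 2.42 at 24 h) and in resistant cells with DMSO (165 ± 3.89 and 127 ± 6.04). The first principal component held 43.8% of the variance and separated the times, with the 8 h libraries between -50.2 and -14.6 and the 24 h libraries between 13 and 64.4. The second held 24.5%. Expression of a library relative to the mean of all libraries correlated across genes with transcript GC content, from -0.6 to 0.52 depending on the library, and libraries of one group differed in this respect.

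The first question was how naive cells responded to the drug. After 8 h, MYC targets and ERK output genes fell in naive cells, and interferon and class II antigen presentation genes rose. Of 54 tested MYC targets, which build ribosomes and nucleotides, 48 fell and 0 rose (49 adjusted over the list alone; median log2 change -0.46, camera adjusted p = 1.28e-27). Among them SRM, a polyamine synthesis enzyme, went from 250 ± 13.7 to 134 ± 24.6 CPM (SD, n = 3). MRTO4 went from 153 ± 8.03 to 89.1 ± 11.9 CPM. MYC itself went from 480 ± 6.36 to 380 ± 20.6 CPM (log2 change -0.34 ± 0.06 SE, adjusted p = 0.00066). Transcripts that follow ERK fell in 11 of 16 (median -0.77), led by ETV4 (-2.09 ± 0.19) and SPRY4 (-2.56 ± 0.32). DUSP6, an ERK phosphatase, did not pass the test (0.14, adjusted p = 0.287). Among STAT5 and FLT3 targets 10 of 18 fell and 1 rose. The kinase gene PIM1 dropped from 204 ± 11.5 to 95.3 ± 12.7 CPM and CISH, a STAT5 feedback inhibitor, from 62.8 ± 3.53 to 38.4 ± 4.67 CPM. The repressor BCL6 rose (log2 1.31 ± 0.29). The list does not mark which members its regulators raise or lower.

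Metabolic genes fell in the same comparison. Amino acid and stress-response genes driven by ATF4 fell in 13 of 26 (median -0.41), among them the serine enzyme PSAT1 (82.3 ± 3.04 to 47 ± 1.72 CPM) and the transporter SLC7A5 (523 ± 19.3 to 273 ± 39.4 CPM). Cholesterol synthesis genes fell in 12 of 24 (median -0.42), with DHCR7, a late enzyme of the pathway, at -1.23 ± 0.13 and INSIG1 at -0.44 ± 0.06. DNA replication and mitosis genes fell in 16 of 40 and rose in 2 (median -0.18), with MCM4 at -0.43 ± 0.05 and CDC45 at -0.58 ± 0.06. Glucose-use genes fell in 14 of 28 and rose in 2 (median -0.26), led by HK2 at -0.56 ± 0.06, with adjusted p = 0.067 with an estimated correlation. Inflammatory genes fell in 7 of 21, with CCL2 at -1.24 ± 0.14 and TNF at -0.86 ± 0.11, and adjusted p = 0.0816 with an estimated correlation.

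Genes that rose in naive cells at 8 h included interferon-stimulated genes, 20 of 40 with none falling (23 adjusted over the list alone; median 0.58, camera adjusted p = 1.11e-12). TRIM22 reached 15.6 ± 1.17 from 6.36 ± 0.24 CPM and STAT2 189 ± 7.65 from 106 ± 2.97 CPM. Class II antigen presentation genes rose in 6 of 12 (median 0.41), including the protease CTSS (0.84 ± 0.08) and HLA-DRA (0.35 ± 0.08). FOXO targets rose in 8 of 22 (median 0.30), with TXNIP, which limits glucose uptake, at 897 ± 57.6 against 510 ± 11.4 CPM and the cyclin CCNG2 at 1.73 ± 0.25. Toll-like receptor pathway genes rose in 6 of 22 and 1 fell (median 0.23), with TLR4 at 0.69 ± 0.13. Myeloid markers rose in 9 of 30, among them the receptor CSF1R (98.9 ± 5.51 against 48.1 ± 1.69 CPM) and CD36 (0.83 ± 0.15), with adjusted p = 0.163 with an estimated correlation. FLT3 rose from 831 ± 27.8 to 1149 ± 70.9 CPM. It and JMJD1C were the 2 members of the HOXA and MEIS1 list that rose (adjusted p = 0.465 with an estimated correlation). In the SYK signalling list 6 of 26 members rose and 1 fell, with PLCG2 at 0.37 ± 0.06 (adjusted p = 0.0702 with an estimated correlation). The single genes with the largest rises were CD84, a SLAM-family receptor (17.6 ± 2.13 against 3.97 ± 0.40 CPM, 4.4-fold), METTL7A, CCNG2, ZMAT1, ENHO, TMEM71, SAMD9L and DNASE2. Those with the largest falls were OCSTAMP (-2.27 ± 0.20), INHBE, ETV4, STC2, STON1, THBS1, ADM2 and FLT1. In all, edgeR's quasi-likelihood test called 3013 of 13440 genes at an adjusted p under 0.05, of which 1437 rose and 1576 fell. By size, 223 rose and 82 fell by 1 log2 unit or more. The split was 1895 to 1192 with upper-quartile factors and 958 to 394 with library totals only, and 1873 genes were called without naive drug 8 h replicate 2. With the GC correction, added after seeing the data, 4504 genes were called, among them 94.5% of those called without it. List medians were then -0.47 for MYC targets, 0.52 for interferon genes and 0.18 for FOXO targets. The HOXA and MEIS1 list was not called (camera adjusted p = 0.0663).

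**Figure D1:**
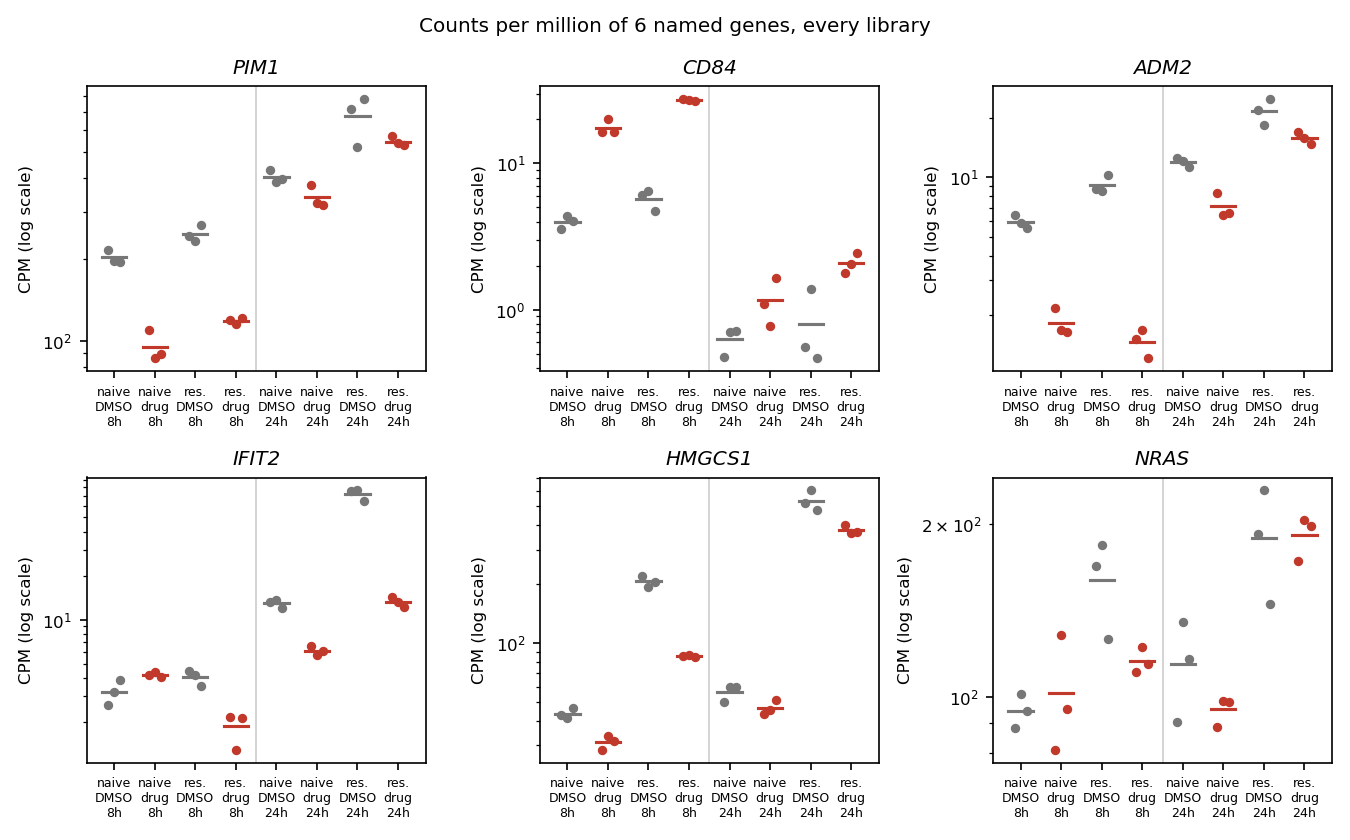
Scaled counts (CPM), on a log axis, of 6 genes in each of the 24 libraries (points) with the group mean (bar), for DMSO in grey and drug in red, with 8 h at left and 24 h at right of each panel. PIM1 and ADM2 lay lower and CD84 higher with the drug in both lines at 8 h, and IFIT2 in resistant cells at 24 h averaged 72.4 CPM with DMSO and 13.2 CPM with the drug.

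After 24 h the response of naive cells was smaller. ERK output genes fell in 3 of 16 (8 adjusted over the list alone; median -0.47), with ETV5 at 7.65 ± 0.53 against 13 ± 0.51 CPM and ETV4 at -0.91 ± 0.19. ATF4 genes fell in 9 of 26 (14 adjusted over the list alone; median -0.23), among them the cystine transporter SLC7A11 (23.9 ± 2.4 against 47.3 ± 8.35 CPM), and cholesterol genes in 4 of 24 (median -0.19), with INSIG1 at -0.42 ± 0.06 and MSMO1 at -0.91 ± 0.19. MYC targets fell in 5 of 54 (median -0.12), with HSPD1, a mitochondrial chaperone, at -0.36 ± 0.07, and adjusted p = 0.11 with an estimated correlation. Of the interferon list, IFIT2 (6.11 ± 0.43 against 12.9 ± 0.86 CPM) and IFIT3 were among 4 that fell, and STAT2 (0.34 ± 0.08) was among 2 that rose. The list's median was -0.12, and its call was lost with an estimated correlation (adjusted p = 0.161). That correlation gave the same adjusted p = 0.161 for the STAT5 and FLT3 targets (1 of 18 fell), glucose-use genes (4 of 28 fell), class II genes (1 of 12 rose, CIITA at 0.64 ± 0.16) and myeloid markers (3 of 30 rose, 1 fell), and adjusted p = 0.11 for replication genes (2 of 40 fell). PIM1 stood at 340 ± 32.9 against 403 ± 21.4 CPM (adjusted p = 0.22) and MYC at 460 ± 21.8 against 466 ± 25.6 CPM (adjusted p = 0.912). The largest rises were those of SDK2, KIF17, ENHO, RASGRP4, LTK, AIFM3, BAI1 and DPEP2, from 1.56 ± 0.30 (SDK2) down to 1.03 ± 0.21 log2 units. The largest falls were those of TGM2 (-1.13 ± 0.17), OCSTAMP, IFIT2, SLC7A11, IL7R, CR1, FAM129A and ETV4. The test called 591 genes, 341 up and 250 down, with 18 up and 12 down by 1 log2 unit or more. This number was 183 without naive drug 24 h replicate 1, 253 without replicate 2 of that group, and 1053, 193 and 232 without naive DMSO 24 h replicates 1, 2 and 3. It was 145 when only these 6 libraries were fitted, and 1516 (610 up, 906 down) with a GC correction added after seeing the data. The split was 453 to 180 with upper-quartile factors and 46 to 14 with library totals only.

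Whether the resistant cells still responded was the next question. At 8 h they did, in many of the same lists. ERK output genes fell in 13 of 16 (median -0.60, camera adjusted p = 2.53e-15), with the immediate early gene EGR1 at 3.33 ± 0.19 against 13.1 ± 0.53 CPM and ETV4 at -1.72 ± 0.17. PIM1 dropped from 249 ± 16.5 to 119 ± 3.03 CPM. Of 18 STAT5 and FLT3 targets 8 fell, and BCL6 rose. ATF4 genes fell in 21 of 26 (median -0.59), including the asparagine synthetase gene ASNS (72.8 ± 4.99 to 27.1 ± 1.82 CPM) and PSAT1 (-1.18 ± 0.07). Cholesterol genes fell in 16 of 24 (median -0.61), including HMGCS1 (207 ± 13.6 to 86 ± 1.14 CPM) and INSIG1 (-0.91 ± 0.06), and glucose-use genes in 12 of 28 (median -0.23), including the transporter SLC2A3 (71.3 ± 3.39 to 26.8 ± 1.24 CPM). Replication and mitosis genes fell in 19 of 40 (median -0.23), with RRM2 at -0.49 ± 0.07. MYC targets were not called as a list (median -0.08, camera adjusted p = 0.0944), nor were interferon genes (median 0.07, camera adjusted p = 0.0811), but with the GC correction the first list was called lower (adjusted p = 0.0114) and the second higher (adjusted p = 0.0192). MYC did not pass the test (-0.07 ± 0.06, adjusted p = 0.49). Inflammatory genes fell in 8 of 21 and rose in 2, with CCL2 at -1.64 ± 0.13, and adjusted p = 0.0896 with an estimated correlation.

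Class II genes rose in 9 of 12 in the resistant cells at 8 h (median 0.88, camera adjusted p = 2.11e-21), with HLA-DRA at 220 ± 4.8 against 112 ± 8.75 CPM and HLA-DPB1 at 1.30 ± 0.17. Toll-like receptor pathway genes rose in 6 of 22 and 1 fell (median 0.25), with MYD88 at 0.49 ± 0.09. In the SYK signalling list 6 of 26 rose and 1 fell, and SYK itself went from 165 ± 3.89 to 213 ± 2.63 CPM (0.37 ± 0.05). Myeloid markers rose in 7 of 30 and fell in 4 (adjusted p = 0.179 with an estimated correlation), with CSF1R at 0.92 ± 0.11 and TREM1 at -1.67 ± 0.20. FLT3 rose from 1082 ± 14.9 to 1588 ± 25.1 CPM. PTPN11, a phosphatase upstream of RAS, fell by 0.49 (SE 0.11). The largest rises were those of CD84 (27.1 ± 0.45 against 5.73 ± 0.91 CPM), NHSL2, LTK, AOAH, HLA-DPB1, F13A1, AMICA1 and KYNU. The change of CHD4 (-8.21 ± 1.75) rested on the single DMSO library described above. The other largest falls were those of INHBE (-3.55 ± 0.30), ADM2 (-2.62 ± 0.16), FLT1, STON1, CR1, OCSTAMP and GPR97. The test called 2154 genes, 998 up and 1156 down; 99 rose and 216 fell by 1 log2 unit or more. It called 1146 genes without resistant DMSO 8 h replicate 1, the library with the CHD4 counts, and 1221 without replicate 2. Without resistant drug 8 h replicates 1, 2 and 3 it called 1237, 1338 and 1350, and with the GC correction 3389. The split was 1150 to 889 with upper-quartile factors and 1715 to 216 with library totals only, where the median of all genes shifted to 0.214. Library totals include the CHD4 counts of resistant DMSO 8 h replicate 1, which by construction lower the scaled level of its other genes.

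At 24 h interferon-stimulated genes stood out in the resistant cells. With the drug, 23 of 40 fell and none rose (30 adjusted over the list alone; median -0.89, camera adjusted p = 5.53e-120). IFIT2 went from 72.4 ± 6.3 to 13.2 ± 1.03 CPM, OAS2, an antiviral RNA sensor, from 33.4 ± 3.79 to 8.06 ± 0.45 CPM, MX1 from 20.3 ± 3.3 to 4.14 ± 0.69 CPM and IFIT3 from 47.6 ± 5.16 to 12 ± 1.21 CPM. ERK output genes fell in 5 of 16 (median -0.32), with EGR1 at 11 ± 1.53 against 36.5 ± 7.3 CPM. ATF4 genes fell in 4 of 26 (13 adjusted over the list alone; median -0.26), cholesterol genes in 2 of 24 (10 adjusted over the list alone; median -0.24), glucose-use genes in 4 of 28 (median -0.11) and inflammatory genes in 5 of 21 (median -0.21). WARS (-0.43 ± 0.05), HMGCS1 (-0.49 ± 0.09), SLC2A3 (-0.86 ± 0.08) and CCL2 (-1.01 ± 0.15) led these lists. The calls of 5 further lists were lost with an estimated correlation. The adjusted p was then 0.108 for STAT5 and FLT3 targets (0 of 18 called, median -0.15), 0.108 for class II genes (1 of 12 rose), 0.0678 for replication genes (2 of 40 fell), 0.0611 for Toll-like receptor genes (0 of 22 called) and 0.0678 for the T and NK list, of which 3 members were tested and IL7R fell. FLT3 rose from 2014 ± 64.5 to 2535 ± 35.3 CPM, and PIM1 stood at 545 ± 23 against 675 ± 136 CPM (adjusted p = 0.264). CD84, F13A1, DTX4, MPEG1, CACNA2D3, KCNK10, DAPP1 and PIEZO2 had the largest rises, from 1.46 ± 0.31 (CD84) to 0.75 ± 0.17. Of the 8 largest falls 7 belonged to the interferon list. The test called 220 genes, 68 up and 152 down, with 6 up and 47 down by 1 log2 unit or more. It called 21 when only these 6 libraries were fitted, 143 and 132 without resistant drug 24 h replicates 1 and 2, and 509 with the GC correction. The split was 10 to 56 with library totals only.

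**Figure D2:**
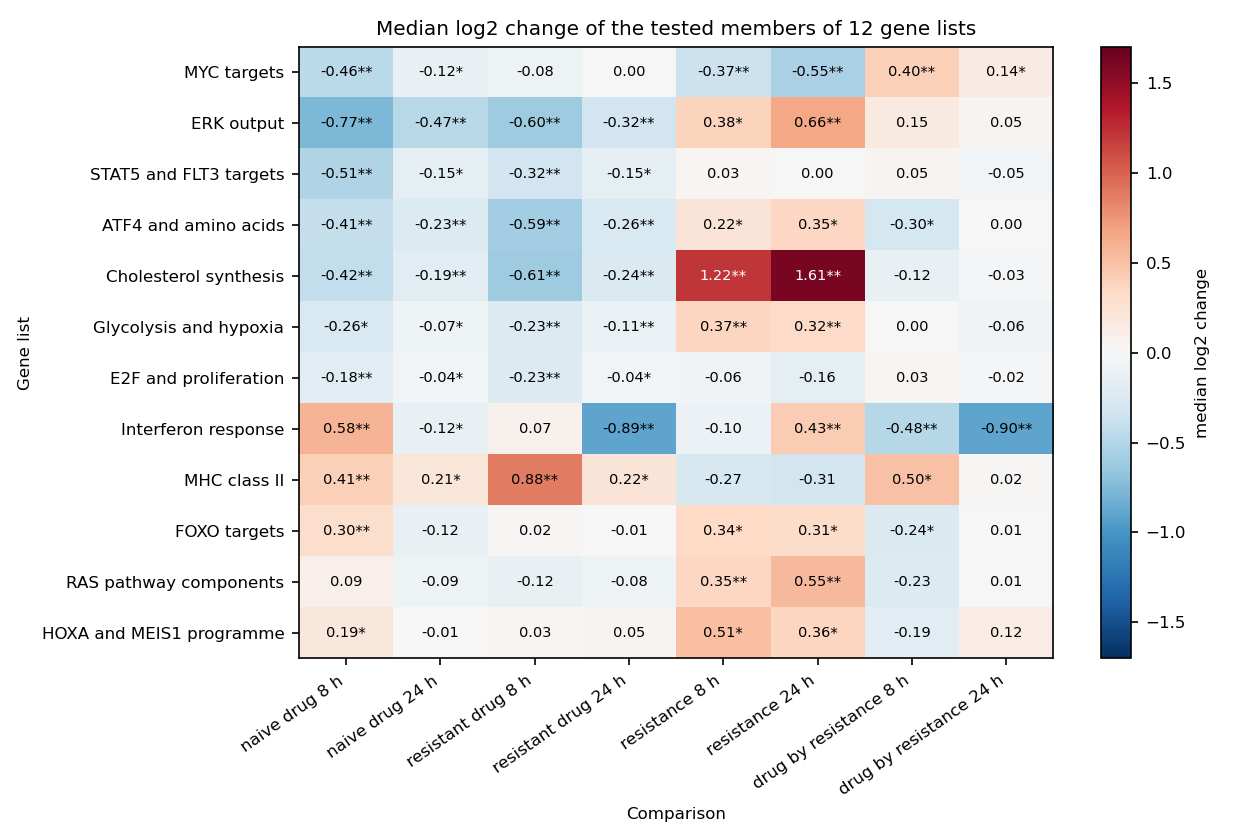
Median log2 change of the tested members of 12 gene lists (rows) in 8 comparisons (columns), as colour and number. An asterisk marks a list called by camera with its preset correlation and 2 asterisks a list also called with an estimated correlation; cholesterol synthesis reached 1.61 in resistant against naive cells at 24 h, and the interferon list -0.89 with the drug in resistant cells at 24 h.

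The difference between the drug responses of the lines was tested as an interaction. At 8 h the MYC targets were the list with the smallest camera p, with 15 of 54 genes showing a less negative response in resistant cells and none the reverse (35 adjusted over the list alone; median difference 0.40, camera adjusted p = 1.2e-18). For SRM the difference was 0.79 ± 0.14 and for MCM4 0.39 ± 0.06. The list's mean level, in log2 units relative to all libraries, was 0.333 with DMSO and -0.164 with the drug in naive cells. In resistant cells it was -0.048 and -0.118. The level with DMSO was thus already lower in resistant cells, and the same DMSO libraries enter the comparison of lines without the drug. Interferon genes responded less positively in resistant cells, in 7 of 40 (median -0.48), with GBP4 at -1.43 ± 0.19 and IFIT2 at -1.48 ± 0.24. HLA-DRA rose more in resistant cells (0.63 ± 0.11), and 3 of 12 class II genes differed (median 0.50, adjusted p = 0.0672 with an estimated correlation). ATF4 genes fell more in 6 of 26 (median -0.30, adjusted p = 0.268 with an estimated correlation), with ASNS at -0.82 ± 0.12, and FOXO targets responded less positively in 5 of 22 (median -0.24, adjusted p = 0.227 with an estimated correlation), with CCNG2 at -1.79 ± 0.33. SYK (0.36 ± 0.08) and DUSP6 (-0.44 ± 0.13) differed, and PIM1 did not pass the test (0.03 ± 0.16, adjusted p = 0.906). CPNE7, ECE2, CCDC78, PYCRL and TLCD1 had the most positive differences and CHD4, N4BP2L2-IT2, ORM1, GPR97 and CCNG2 the most negative. The value of CHD4 came from 1 library. In all 603 genes differed, 296 positively and 307 negatively. Leaving out any of the 12 libraries moved this count by over 1.5 times, from 177 without naive drug 8 h replicate 2 to 2011 without naive drug 8 h replicate 1, and the GC correction gave 1789 (1224 positive, 565 negative). The split was 226 to 369 with upper-quartile factors, 439 to 300 with RLE factors and 508 to 300 without CHD4.

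At 24 h interferon genes were among those that differed. Of 40 tested, 12 responded more negatively in resistant cells (28 adjusted over the list alone; median -0.90, camera adjusted p = 9.79e-53), with OAS2 at -1.68 ± 0.14, MX1 at -1.96 ± 0.19, MX2 at -1.45 ± 0.20 and IFIT2 at -1.35 ± 0.19. The MYC target list was also called (median 0.14) with 0 of 54 members called, and adjusted p = 0.179 with an estimated correlation. The positive differences were those of ALDH1A3, a retinoic acid enzyme (0.69 ± 0.12), and FABP5, a fatty acid carrier (0.60 ± 0.12). OAS1 and IFI44 completed the 5 most negative. The test called 33 genes, 2 positive and 31 negative. It called 10 without resistant drug 24 h replicate 2, 124 and 15 without resistant DMSO 24 h replicates 2 and 1, 16 and 21 without naive drug 24 h replicates 1 and 2, and 59, 19 and 19 without naive DMSO 24 h replicates 1, 2 and 3. DESeq2 called 144, and the GC correction gave 195 (100 positive, 95 negative).

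Within naive cells the response at 24 h minus that at 8 h was tested in the same way. Interferon genes rose in 20 of 40 at 8 h and in 2 at 24 h, and 13 of 40 had a negative difference (median -0.72), with OAS2 at -1.19 ± 0.14 and SAMD9L at -1.68 ± 0.31. MYC targets fell less at 24 h, in 10 of 54 (28 adjusted over the list alone; median 0.40), with NOP16 at 0.68 ± 0.14, and PIM1 likewise (0.86 ± 0.16). FOXO targets responded less positively in 3 of 22 (median -0.34), with TXNIP at -0.59 ± 0.09. For 7 further lists the call was lost with an estimated correlation: cholesterol genes (2 of 24 positive, DHCR7 at 0.84 ± 0.18, adjusted p = 0.0568), replication genes (3 of 40, adjusted p = 0.0568), ERK output (3 of 16, adjusted p = 0.145), ATF4 genes (1 of 26, adjusted p = 0.354), inflammatory genes (1 of 21, adjusted p = 0.354), glucose-use genes (0 of 28, adjusted p = 0.359) and the HOXA and MEIS1 list (0 of 17, adjusted p = 0.356). STC2, DDN, STON1, ETV4 and SLC38A5 had the most positive differences and CCNG2, PKIB, SAMD9L, FAM214A and KIAA1107 the most negative. The test called 212 genes, 128 positive and 84 negative, with a range of 50 to 1115 when single libraries were left out, the ends without naive drug 8 h replicate 2 and replicate 1; each of the 12 moved the count by over 1.5 times. The split was 102 to 112 with upper-quartile factors and 2 to 10 with library totals only. The 8 h and 24 h libraries also differed with DMSO alone, in 4509 genes in naive cells.

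The last set of comparisons asked how resistant cells differed from naive cells without the drug. The labels distinguish only a single resistant derivative, so these differences describe that derivative and do not separate resistance from its other changes. Cholesterol synthesis genes were higher in resistant cells at both times, in 21 of 24 at 8 h (median 1.22, camera adjusted p = 7.87e-41) and 23 of 24 at 24 h (median 1.61, camera adjusted p = 1.79e-55). A single member was lower at each time. HMGCS1, an early enzyme of the pathway, stood at 207 ± 13.6 against 43.6 ± 2.68 CPM at 8 h and at 533 ± 63.9 against 56.4 ± 5.36 CPM at 24 h (9.43-fold). INSIG1 differed by 1.73 ± 0.06 and 2.19 ± 0.06, and CYP51A1 by 2.18 ± 0.10 and 2.33 ± 0.10. Glucose-use and hypoxia genes were higher in 15 of 28 at 8 h and 16 of 28 at 24 h, with none lower (medians 0.37 and 0.32). SLC2A3 reached 71.3 ± 3.39 against 14.2 ± 0.43 CPM at 8 h and 89.2 ± 4.86 against 10.4 ± 0.54 CPM at 24 h, and BNIP3 and NDRG1 rose with it (1.87 ± 0.08 and 1.65 ± 0.07 at 8 h). MYC targets were lower, in 37 of 54 at 8 h (median -0.37) and 42 of 54 at 24 h (median -0.55), with SRM at -0.79 ± 0.10 and -1.19 ± 0.10. TMEM97, a member of that list and a sterol-regulated gene, was the only higher member at 24 h (1.01 ± 0.08), and 2 members were higher at 8 h. MYC itself did not pass the test at 8 h (-0.01 ± 0.06, adjusted p = 0.882) and was higher at 24 h (574 ± 13.6 against 466 ± 25.6 CPM).

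ERK output genes were higher in resistant cells, in 7 of 16 at 8 h (median 0.38, adjusted p = 0.0632 with an estimated correlation) and 13 of 16 at 24 h (median 0.66). DUSP6 differed by 0.78 ± 0.09 and 0.87 ± 0.09, ETV5 by 0.94 ± 0.10 and 1.11 ± 0.10, and EGR1 by 0.73 ± 0.14 and 2.88 ± 0.14. Genes coding for parts of the RAS cascade were higher in 16 and lower in 4 of 27 at 8 h (median 0.35), and higher in 15 and lower in 6 at 24 h (median 0.55). With the GC correction the list's medians were 0.15 and 0.25. NRAS stood at 160 ± 30.1 against 94.8 ± 6.49 CPM at 8 h and 189 ± 41.9 against 114 ± 22.3 CPM at 24 h. With the GC correction the NRAS difference went from 0.75 to 0.25 (SE 0.07) at 8 h and from 0.72 to 0.31 (SE 0.07) at 24 h. ARAF was lower at both times (-0.64 ± 0.09 and -0.58 ± 0.09), and NF1, which switches RAS off, was higher at 8 h (1.18 ± 0.15). PTPN11 was higher at 8 h (0.38 ± 0.11), a call that ended with the GC correction (0.09, adjusted p = 0.206), and did not pass the test at 24 h (adjusted p = 0.205). FLT3 was higher at both times (0.38 ± 0.06 and 0.31 ± 0.06), as was PIM1 (0.29 ± 0.11 and 0.74 ± 0.11).

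Interferon genes were higher in resistant cells at 24 h, in 25 of 40 with 4 lower (median 0.43), led by IFIT2 (72.4 ± 6.3 against 12.9 ± 0.86 CPM) and IFIT3. The list was not called at 8 h. Its mean level at 24 h, in log2 units relative to all libraries, was 0.812 in resistant and 0.269 in naive cells with DMSO. With the drug it was lower in resistant (-0.266) than in naive cells (0.134). The drug comparison in resistant cells and the difference between lines at 24 h use the same resistant DMSO libraries. So does the comparison of times with DMSO in resistant cells. In the HOXA and MEIS1 list 13 of 17 were higher at 8 h and 12 at 24 h, but the adjusted p was 0.329 and 0.347 with an estimated correlation. BCL2 (0.60 ± 0.09 and 0.57 ± 0.09), CDK6 at 8 h (1.01 ± 0.17) and MEF2C at 24 h (0.75 ± 0.13) were among the higher members, HOXA9 was the lower one at 8 h (-0.75 ± 0.17), and MEIS1 did not pass the test (0.15 ± 0.09 at 8 h, adjusted p = 0.186). With the GC correction MEIS1 was called lower at 8 h (-0.17 ± 0.07, adjusted p = 0.0414). ATF4 genes (9 of 26 higher at 8 h and 15 at 24 h) had adjusted p of 0.433 and 0.186 with an estimated correlation, and FOXO targets (11 and 12 of 22 higher) 0.283 and 0.123. ATF5 and DDIT4 led the first at 8 h (1.23 ± 0.10 and 1.58 ± 0.17) and KLF6 and KLF2 the second at 24 h (1.69 ± 0.13 and 2.50 ± 0.24). Stem and progenitor markers were higher in 3 of 6 tested members at 24 h, among them GATA2 (0.97 ± 0.09), with adjusted p = 0.0638 with an estimated correlation. SYK was lower at 24 h (-0.18 ± 0.05) and did not pass the test at 8 h (adjusted p = 0.573). Besides the sterol genes MSMO1 and STARD4, DHRS3 and GNG2 had the largest differences at 8 h, and FN1, C6orf223 and KLF2 at 24 h. For FN1 the SD exceeded the mean in resistant cells (18.9 ± 26.1 CPM), and the value of CHD4 at 8 h (8.26 ± 1.75) came from 1 library. The lowest relative to naive cells were ALOX5, a leukotriene enzyme (-1.72 ± 0.13), MICALL2, IL7R, CCDC78, ENDOG, HSPA1A, IGFLR1 and PRR22 at 8 h. At 24 h they were CILP2 (-2.06 ± 0.18), DNLZ, ENDOG, SLC27A4, TYMP, FAM219A, FAM86A and FAM173A. The test called 6651 genes at 8 h (3498 up, 3153 down) and 6649 at 24 h (3389 up, 3260 down). With the GC correction it called 5836 (2556 up, 3280 down) and 6538 (2968 up, 3570 down), and these included 63.3% and 74.6% of the genes called without it. Across genes the 2 log2 changes correlated at r = 0.74, and 2499 genes were up and 2393 down at both times, against 882 and 764.8 for independent lists. The log2 changes correlated with GC content across genes at -0.53 and -0.43, and at 24 h 2787 genes were called when only those 6 libraries were fitted. With library totals only the split at 8 h was 1296 to 4105, and the median of all genes shifted to -0.219. These totals include the CHD4 counts of resistant DMSO 8 h replicate 1, which were 35.48% of that library. By construction such counts lower the scaled level of its other genes.

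A response score set the lines side by side. Over the 30 genes that changed most in naive cells at 24 h, the mean signed log2 difference from DMSO at 8 h was 0.82 ± 0.10 (SD, n = 3) in naive and 0.82 ± 0.02 in resistant cells, a difference of 0 (exact permutation test, two-sided p = 1). Without naive DMSO 24 h replicate 1 these scores were 0.54 and 0.65. Over the 305 genes that changed most in naive cells at 8 h, the score at 24 h was 0.35 ± 0.02 in naive and 0.19 ± 0.01 in resistant cells, with the naive libraries above the resistant ones in 3 of 3 (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 allows). All scores of a line and time share the mean of its DMSO libraries, so these SDs and tests leave out the spread of the DMSO libraries. With single DMSO 24 h libraries of the scored line left out, the score at 24 h was 0.32 to 0.4 in naive and 0.13 to 0.24 in resistant cells. Over genes chosen in resistant cells at 24 h instead, the score at 8 h was 0.19 ± 0.03 in naive and 0.83 ± 0.02 in resistant cells, and over those chosen at 8 h the score at 24 h was 0.35 ± 0.05 and 0.36 ± 0.14. The size of the difference thus depended on the line in which the genes were chosen. With genes chosen in naive cells at an adjusted p alone, the scores were 0.49 and 0.45 at 8 h and 0.17 and 0.07 at 24 h.

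**Figure D3:**
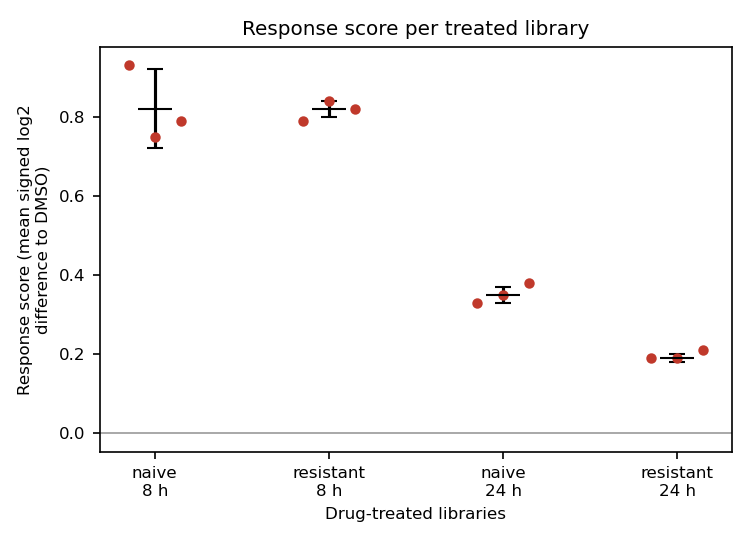
Response score (mean signed log2 difference to DMSO over genes chosen in naive cells at the other time) of each drug-treated library (points), with the mean and SD of 3 libraries (bar and whiskers). The naive libraries scored 0.33 to 0.38 at 24 h and the resistant ones 0.19 to 0.21, while the means at 8 h were both 0.82.

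Across all genes, the drug's log2 changes in naive and resistant cells correlated at r = 0.27 at 8 h and 0.16 at 24 h, comparisons that share no library; genes are not independent replicates, and no p-value is given. The value at 8 h was 0.17 without naive DMSO 8 h replicate 2 or without resistant DMSO 8 h replicate 3, and that at 24 h was 0.04 without resistant DMSO 24 h replicate 2. With the GC correction the values were 0.37 at 8 h and 0.17 at 24 h. Of the called genes, 465 rose and 391 fell in both lines at 8 h, against 106.7 and 135.6 for independent lists, and 13 and 5 went in opposite ways. At 24 h 34 rose and 40 fell in both, against 1.7 and 2.8. The drug's changes in naive cells at 8 h correlated at 0.36 with the difference between resistant and naive cells at 24 h, with 731 genes up and 975 down in both against 362.4 and 382.3. This correlation was 0.22 without naive drug 8 h replicate 2 and 0.29 with the GC correction. The drug's changes in naive cells at 24 h and that difference at 8 h correlated at -0.15, with 84 up and 58 down in both against 88.8 and 58.6, and the sign turned with the GC correction (0.03) and without naive DMSO 24 h replicate 2 (0.01). It was -0.23 without naive DMSO 24 h replicate 1 and -0.07 without naive drug 24 h replicate 1.

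Lists of markers of other cell types were tested too. In the 6 pairwise comparisons no B lymphoid list (6 tested members), erythroid and megakaryocyte list (4) or epithelial and stromal list (7) was called. The mean level of the last list, in log2 units relative to all libraries, was 1.733 in resistant DMSO 24 h replicate 1 and 1.817 in resistant drug 24 h replicate 2, against -0.49 to -0.039 in the other resistant libraries at 24 h. COL1A1, a collagen gene named after its values were seen, reached 10.2 and 24.07 CPM in those 2 libraries. The T and NK list had 3 tested members, CD4, IL7R and NKG7. IL7R fell with the drug in naive cells (49.9 ± 2.96 to 22.8 ± 0.66 CPM at 8 h) while CD4 rose (0.26 ± 0.07), and the list's call was lost with an estimated correlation at 8 h (adjusted p = 0.0816) and 24 h (adjusted p = 0.0884). The list was called lower in resistant cells at 8 h (median -0.68, adjusted p = 0.00934 with an estimated correlation), with IL7R at -1.57 ± 0.09 and NKG7 at -0.68 ± 0.16. Apoptosis regulators of the BCL2 family (15), p53 targets (23), drug efflux transporters (7) and replication-dependent histones (11) were not called as lists in these comparisons; of the efflux transporters 0 rose and 2 were lower in resistant cells at each time.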

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

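The GC tests, the window test within one time, the window correlation in random gene orders, the count of splits without reversed labels and the comparison of times with DMSO were chosen after the results were seen. Each result in this paragraph drew attention because the response differed between lines or times in the interaction test. At 8 h the lines differed in 603 genes. The lists that differed were MYC targets (median 0.4), interferon genes (-0.48), class II genes (0.5), ATF4 genes (-0.3) and FOXO targets (-0.24), the calls of the last 3 being lost with an estimated correlation. Single genes were SYK (0.36), DUSP6 (-0.44), CPNE7 (1.25), ECE2 (1.23), CCDC78 (1.21), PYCRL (1.13), TLCD1 (1.12), CHD4 (-8.28), N4BP2L2-IT2 (-2.03), ORM1 (-1.86), GPR97 (-1.8) and CCNG2 (-1.79). At 24 h the lines differed in 33 genes and in the interferon list (-0.9); the MYC list (0.14) was called with 0 members called and lost its call with an estimated correlation. Single genes were ALDH1A3 (0.69), FABP5 (0.6), MX1 (-1.96), OAS2 (-1.68), OAS1 (-1.6), IFI44 (-1.55) and MX2 (-1.45). The response of naive cells differed between times in 212 genes. Single genes were PIM1 (0.86), STC2 (1.37), DDN (1.28), STON1 (1.25), ETV4 (1.17), SLC38A5 (1.05), CCNG2 (-1.85), PKIB (-1.77), SAMD9L (-1.68), FAM214A (-1.47) and KIAA1107 (-1.45). Lists were ERK output (0.34), MYC targets (0.4), the HOXA and MEIS1 list (-0.28), inflammatory genes (0.17), interferon genes (-0.72), replication genes (0.12), cholesterol genes (0.29), ATF4 genes (0.27), FOXO targets (-0.34) and glucose-use genes (0.18). Of these only the MYC, interferon and FOXO lists kept their call with an estimated correlation.

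Other splits of the libraries were counted for each of these numbers, the real split included. At 8 h 10 of 100 splits called at least 603 genes, the highest other 3609. At 24 h 13 of 100 reached 33, the highest other 2284, and for the time difference 14 of 100 reached 212, the highest other 3042. Of the other splits that reached these numbers, 7, 11 and 8 set the drug labels of one side against those of the other, which moves the shared drug response into the difference. Among splits without that reversal, 3 of 42, 2 of 47 and 6 of 50 reached the real number. Splits without that reversal can still mix the drug labels of the sides unequally. Part of the shared response then stays in the difference, so neither count can decide about chance. At 24 h the 2 counts also lay on different sides of a share of 0.05. Chance was thus not excluded for any of these numbers, and the question stays open. The 24 h split with 2284 genes had no such reversal. Unequal mixing of the labels or a structure of the samples beyond their groups may lie behind it, which was not tested. For pairwise comparisons 10 splits are too few for a share under 0.05. The real split and the highest other gave 3013, 591, 2154, 220, 6651 and 4509 genes against 0, 6649 against 2967 (resistance at 24 h) and 5030 against 1430 (time in resistant DMSO).

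Libraries at 24 h differed from those at 8 h in runs of neighbouring genes. After GC correction, the means of 40-gene windows had an SD of 0.186 in naive DMSO cells, against 0.083 at most in random gene orders. The fitted GC trend alone would thus not give it. That trend is an average over genes, so the correction cannot exclude GC content as a source. Window means correlated at 0.94 between naive and resistant drug-treated cells, but at 0.74 to 0.88 in random gene orders, so any effect of time shared by the lines passes this test. The drug response of naive cells at 8 h, within one time, also had a window SD (0.062) above the highest random value (0.056). An SD above the random orders thus does not decide either. In size the comparisons differed. Between times the SD was 0.185 to 0.188 over lines and agents, against highest random values of 0.083 to 0.094. Within one time it was 0.054 to 0.081, against 0.051 to 0.074. Whether cell stocks that differ in gene dosage or hours in culture gave the difference is open, and comparisons within one time do not cross it. The difference between times in naive cells, and the response score with genes chosen at the other time, combine libraries of both times.

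NRAS was higher in resistant cells. After GC correction the difference at 8 h was 0.25, so the fitted GC trend may carry part but not all of it. That trend is an average over genes, so it cannot exclude that GC content carries the rest. No biological explanation was tested.

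Interferon genes were lower with the drug in resistant cells at 24 h. Among the 8 groups the list's mean level was highest in resistant DMSO cells at 24 h (0.812, in log2 units relative to all libraries). These DMSO libraries enter both the drug comparison and the difference between lines. Leaving out any single library kept the call of the difference between lines (highest adjusted p = 6.65e-35), and its GC-corrected median was -0.9. In resistant cells the list's median change from 8 h to 24 h was 1.08 with DMSO and -0.11 with the drug, a difference of medians of 1.19. Gene by gene this is the drug's effect at 8 h minus that at 24 h by construction, so it decides nothing about the origin of the pattern, which remains open.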

How the results depend on the processing

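Counts moved under many alternatives, and 3 values, given below, reversed. The GC correction and the other alternatives outside the plan, which are named in the processing section, were chosen after the data were seen. The larger direction of the calls turned, and the size of the score difference between lines changed, under some settings, with the values in the results. With library totals only, the counts were 1352 (naive drug 8 h), 60 (naive 24 h), 66 (resistant 24 h), 32 and 10 (difference between lines at 8 h and 24 h), 12 (difference between times) and 3004 (DMSO time, naive), and the response scores 0.94, 0.39, 1.14 and 0.23 for naive 8 h, naive 24 h, resistant 8 h and resistant 24 h. With no filter naive 24 h gave 375 and the time difference 135. A block for the replicate number gave 1054, 1706 (lines, 8 h) and 699 (times), but the samples share only a number. Of 84 pairs with the same number 33 correlated over 0.1 (median 0.06, against -0.03 for other numbers), and 15 of 24 libraries were closest to their own number, a hint from the data and not from the design. The GC correction gave 1516, 3389 (resistant 8 h), 509, 1789, 195 and 628, and scores of 0.43, 0.65 and 0.21 in naive 24 h, resistant 8 h and resistant 24 h. Thinning, with CHD4 removed at the same time, gave 235, 1163, 112, 205, 6 and 78, DESeq2 966, 1410, 144 and 730, and fitting only the groups compared 145, 21, 2787 (resistance 24 h), 1465, 5 and 2432 (DMSO time, resistant), in the last case with fewer samples by construction. Genes chosen at an adjusted p alone gave scores of 0.49, 0.17, 0.45 and 0.07, and genes chosen in resistant cells 0.19 (naive 8 h) and 0.36 (resistant 24 h). Over genes called in either line, the correlations between lines were 0.45 at 8 h and 0.4 at 24 h. Reversed values were MEIS1 in resistant against naive cells at 8 h (-0.17 with the GC correction) and the correlation of naive drug 24 h with resistance at 8 h (0.03 with the GC correction, 0.01 without naive DMSO 24 h replicate 2). Leaving out single libraries gave 1873 to 3527, 183 to 1053, 1146 to 3047 and 132 to 305 genes for the drug in naive 8 h, naive 24 h, resistant 8 h and resistant 24 h, 4817 to 7193 and 4918 to 7446 for resistance, 177 to 2011 and 10 to 124 between lines, 50 to 1115 between times, and scores of 0.54 to 0.85, 0.31 to 0.43, 0.65 to 0.98 and 0.13 to 0.24. Calls of named genes that ended and that were gained were 362 and 43 when single libraries were left out (counted for each library), 127 and 2 with library totals only, 78 and 1 with thinning, 77 and 2 with only the groups compared, 23 and 0 with no filter, 9 and 33 with the GC correction, 1 and 19 with DESeq2, 0 and 20 with the block and at most 5 in each other setting. For lists they were 48 and 35 when single libraries were left out, 48 and 0 with an estimated correlation, 16 and 4 with library totals only, 6 and 44 with fry, 6 and 12 with the GC correction, 5 and 9 with no filter and at most 3 in each other setting. Removing CHD4 alone moved no count by over 1.5 times. The 4 correlations ranged over 0.17 to 0.31, 0.04 to 0.21, 0.22 to 0.39 and -0.23 to 0.01. Except where construction is named, the cause was not tested.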

Other observations

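With DMSO alone, 4509 genes differed between 24 h and 8 h in naive cells (2382 higher, 2127 lower) and 5030 in resistant cells, a comparison added after seeing the data. Class II antigen presentation genes were lower at 24 h in 10 of 12 in each line (medians -2.42 and -2.30), with HLA-DPA1 at -3.74 ± 0.12 in naive and -4.01 ± 0.13 in resistant cells. Interferon genes were higher in 22 of 40 in naive and 32 of 40 in resistant cells (medians 0.57 and 1.08). AKR1C3, a steroid enzyme, differed by 4.68 ± 0.17 and 5.07 ± 0.18, and CCND2, a cyclin, by -4.78 ± 0.17 and -4.34 ± 0.16. Across genes the changes of the 2 lines correlated at 0.83. In the library with most CHD4 counts, genes named here after their values were seen stood higher: SENP3 was 2.67, MTA2 1.84, KCNQ1OT1 1.18, SHISA9 1.11 and DGKH 1 log2 units above both other libraries of the group.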
